A study of Rattus norvegicus with 83 samples.

How the data were processed

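RNA from rat offspring, labelled testis, was measured in 83 libraries of 10 groups (2 labelled stages, vehicle and 2 doses each of methimazole and amitrole). Per the labels' protocols, dams were dosed by gavage from gestational day 7 to pup day 22 with birth expected on gestational day 23, and libraries were made by bulk RNA barcoding with pooled 3′-end sequencing. Per the submitters' processing notes, reads were aligned to rn6 with BWA 0.7.4.4. The deposited table holds raw counts per gene symbol and library, per the labels. The counting tool, annotation, strand setting and handling of molecular barcodes are not given in the sources used here. Litter and animal identities are not given either. The table has 17483 symbols, of which 15578 matched current RefSeq rat gene names and 1556 more matched as synonyms, used for names only. The reference available here is of another build than rn6, so no coordinates were used.

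Median total counts were 1097632, 1114057.5, 1014444.5, 797417.5 and 864012.5 for vehicle, MMI8, MMI16, Ami25 and Ami50 at GD21, and 627048.5, 391745.5, 487567.5, 551457 and 457019.5 at PD16. The median number of genes with a count was 10352 at GD21 and 9333 at PD16. At the PD16 median total of 492083, 1 count is about 2 CPM, so genes of a few CPM rest on single counts. Libraries of the same group were compared for duplication with a chi-square per gene over 331 pairs, and the lowest value per degree of freedom was 1.565, so no library was a copy of another of its group; pairs across groups were not compared.

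Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr on group with a minimum count of 10, which left 6236 genes at GD21, 4906 at PD16 and 6287 over both. Library sizes were scaled with TMM factors, and dispersions, robust quasi-likelihood fits and quasi-likelihood F tests were computed with edgeR. All 5 groups of a stage were fitted together, and all 10 groups for the comparison of vehicle libraries between stages and for the 2 interactions. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Group means and SDs are of counts scaled to the total count of each library (CPM), and the mean of the 270 falling genes is of log2 CPM with TMM factors and a prior count of 2. The test was tested on simulated data with 200 changed genes, and recovered 91.0% of genes changed 2-fold for MMI16 and 92.4% for Ami50 at PD16, with a false share of calls of 7.95% and 4.14%. The changed genes rose and fell in equal number, and each gene was drawn on its own. With 2627 of 4906 genes called for Ami50 at PD16, these rates need not hold for that comparison.

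The 17 comparisons, the test, 24 gene lists, a panel of 18 genes, the rule for naming genes and the first alternatives were fixed before the data were examined. The rule named the 6 largest called rises and falls among genes of at least 20 CPM for MMI16 and Ami50 against vehicle and Ami50 against MMI16 at PD16 (3 each in other comparisons), up to 3 called members per list, and the panel whatever its result. Symbols that are only identifiers were passed over. A gene that the rule named for MMI16 against MMI8 at PD16 is not reported here. Jag1 and Cirbp in Ami50 and the marker genes were named after their values were seen. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, where at least 3 members were tested. Camera with an estimated correlation and fry (directional and mixed) were the alternatives. Lists too small to test at PD16 were those of thyroid hormone receptors and transport (1 gene), immature Sertoli cells (2), pachytene and later germ cells (2), and early meiotic prophase, epididymis and axoneme (0 each). At GD21 early meiotic prophase and epididymis had 1 gene each and axoneme 0. The mitochondrially encoded genes had 0 members in the table.

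The alternatives were DESeq2's Wald test, its size factors in edgeR, no filter, a filter at a mean of 10 CPM, edgeR's legacy fit, fits of only the compared libraries, the library number series as a covariate, and fits without libraries under 0.5 of the stage's median total or without the library farthest from its group. Fits without libraries with Alb at 200 CPM or more, or with Eif2s3y under 10 CPM, were added after the data had been seen. Each count of calls was also set against other splits of the same libraries. No column of the table was left out.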

Results

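Gene expression was measured by bulk RNA barcoding and sequencing (BRB-seq), which tags the 3′ end of polyadenylated RNA with a sample barcode and pools the samples for sequencing. The 83 libraries came from offspring of Sprague-Dawley rats and carry the label testis. The dams had received corn oil as vehicle, methimazole (MMI, 8 or 16 mg/kg body weight per day) or amitrole (Ami, 25 or 50 mg/kg body weight per day) by gavage from gestational day 7. Both compounds inhibit thyroid peroxidase, the enzyme that iodinates thyroglobulin, and amitrole is also an inhibitor of catalase. The libraries labelled gestational day 21 (GD21) numbered 6 in each of the 5 groups. The libraries labelled pup day 16 (PD16) numbered 10 for vehicle, 10 for MMI8, 10 for MMI16, 11 for Ami25 and 12 for Ami50. Total counts per library ranged from 495369 to 1627114 at GD21 (median 963356) and from 202270 to 1186973 at PD16 (median 492083). The labels do not say which animals were littermates, so the p-values measure the spread between these samples.

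The libraries held the transcripts of an adrenal gland at high levels and those of a testis at trace levels. The 15 testis genes examined, among them Amh of Sertoli cells, Insl3 and Cyp17a1 of Leydig cells, Ddx4 of germ cells and Sycp3 of meiotic cells, together had 121 counts among the 57573311 counts of all libraries, and 24 libraries had none. In the library with the most, they reached 11.1 CPM, a count scaled to the library total. Cyp21a1, the steroid 21-hydroxylase of the adrenal cortex, averaged 9510 ± 1120 CPM in GD21 vehicle (SD, n = 6) and 3010 ± 458 CPM in PD16 vehicle (SD, n = 10). Pnmt, which makes adrenaline in the adrenal medulla, averaged 663 ± 106 CPM and 215 ± 40.9 CPM in the same groups. The 6 adrenal cortex genes summed to at least 6305 CPM and the 9 medulla genes to at least 850 CPM in every library. The tissue label therefore went against the data, and the libraries are called here by their labelled stage and treatment only.

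**Figure D1:**
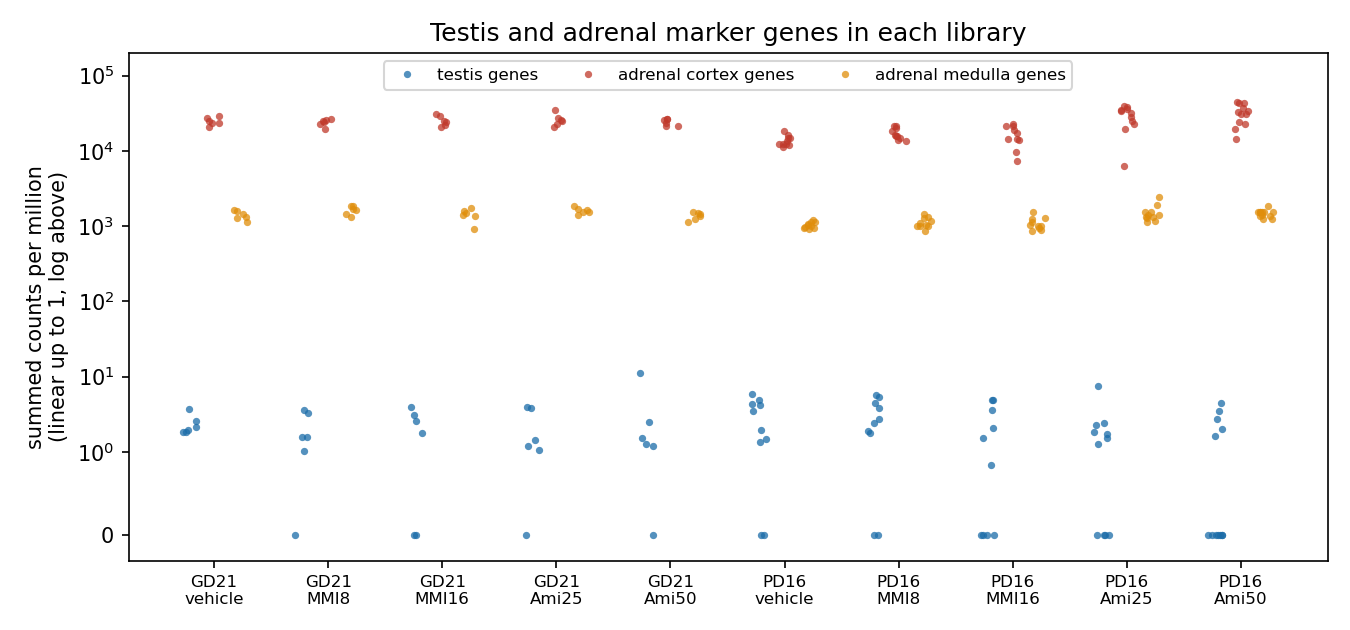
Summed CPM (vertical axis, linear up to 1 and logarithmic above) of testis, adrenal cortex and adrenal medulla genes, with 1 point per library and gene set, in the 10 labelled groups (horizontal axis). The testis genes stay at or below 11.1 CPM in all 83 libraries, while the cortex genes lie at or above 6305 CPM.

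The stage labels, and the male sex that a testis label implies, also met values that went against them. The embryonic globins Hbe1, Hbz and Hbg1, which are made in the yolk sac before birth, took 14.8 ± 2.5% of globin counts in libraries labelled PD16 vehicle (SD, n = 10), 17.0 ± 2.81% in MMI8 (n = 10) and 16.4 ± 4.27% in MMI16 (n = 10). Their share was 0.161 ± 0.05% in GD21 vehicle (SD, n = 6), 0.18 ± 0.0698% in PD16 Ami25 (n = 11) and 0.142 ± 0.0798% in PD16 Ami50 (n = 12). All globins together took 3.81 ± 0.451% of counts in PD16 vehicle and 8.86 ± 1.83% in PD16 Ami50. The Y-linked gene Eif2s3y lay under 10 CPM in 8 of the 12 PD16 Ami50 libraries and in no other library. Alb, the liver's albumin gene, reached 200 CPM or more in 15 libraries, 10 of them labelled GD21 and 5 labelled PD16 (MMI16 1, Ami25 1 and Ami50 3).

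**Figure D2:**
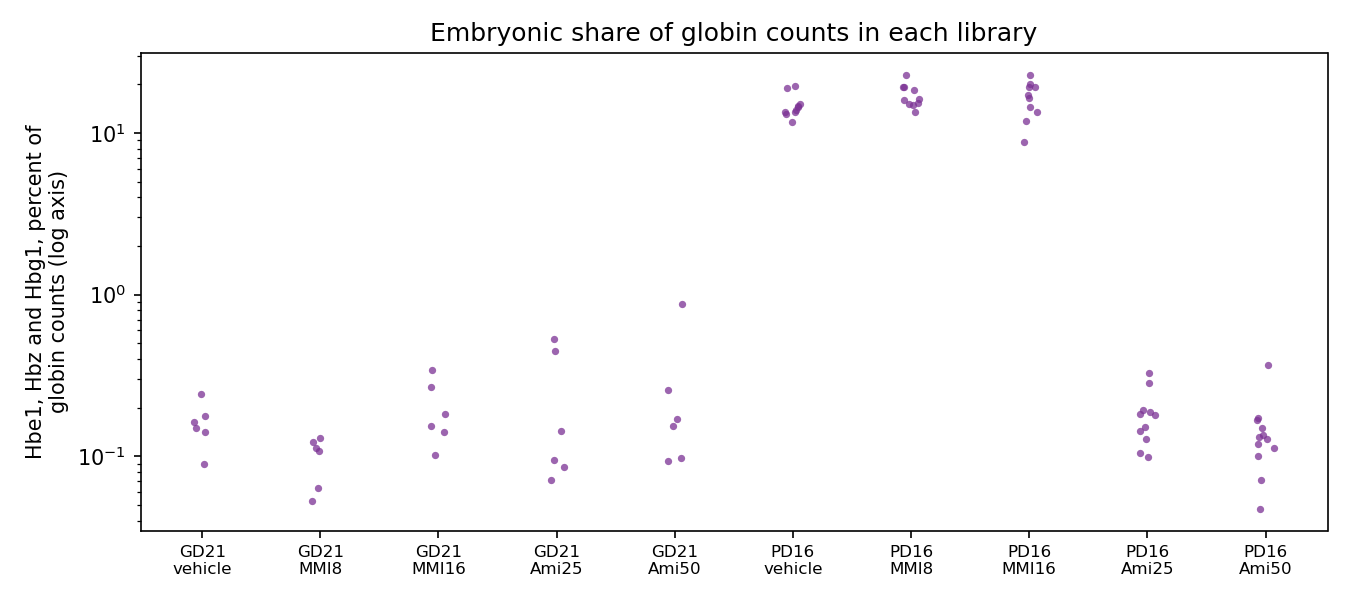
Share of the globin counts taken by Hbe1, Hbz and Hbg1 (vertical axis, percent, logarithmic), with 1 point per library, in the 10 labelled groups (horizontal axis). The libraries labelled PD16 vehicle, MMI8 and MMI16 average 14.8 to 17.0%, and all other groups average 0.275% or less.

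Genes chosen in advance for thyroid hormone signalling and testis development were mostly too low to test. Of 18 such genes, 17 were in the table and 4 passed the filter at PD16 and 6 at GD21. In PD16 vehicle libraries (n = 10) the thyroid hormone receptor genes Thra and Thrb averaged 10.6 ± 6.54 and 2.36 ± 1.66 CPM (SD). The hormone-responsive gene Klf9 averaged 3.71 ± 2.43 CPM and Cdkn1b, a cell cycle inhibitor, 4.19 ± 4.2 CPM. Hr, Amh, Fshr, Cyp17a1, Insl3, Kit and Sycp3 averaged 0.135 to 0.919 CPM in these libraries. Dio3 and Lhcgr had a count of 0 there, which allows up to 0.468 CPM over the pooled group, for counting error only.

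The first question was whether either compound changed expression by GD21. edgeR called no gene at either dose of either compound, DESeq2 called 22 for Ami50, and the steroidogenic gene Star averaged 985 ± 190 CPM in MMI16, 992 ± 186 CPM in Ami50 and 983 ± 57.5 CPM in vehicle (SD, n = 6 each). For Ami50 the fold changes (log2) of the testable preselected genes were 0.06 for Cat (catalase), 0.04 for Star, 0.57 for Sox9, -0.18 for Mki67, -0.39 for Klf9 and -0.71 for Thra. For MMI16 they lay between -0.08 (Thra) and 0.19 (Sox9). Genes of macrophages and other leukocytes shifted upwards as a list against other genes, with a median log2 fold change of 0.34 over 16 genes in MMI16 (camera adjusted p = 0.0104) and 0.65 in Ami50 (adjusted p = 1.14e-07). With an estimated correlation the adjusted p was 0.874 in MMI16 and 0.324 in Ami50. In Ami50 4 of these genes rose when adjusted over the list alone, against 0 over all genes tested. Libraries with Alb at 200 CPM or more numbered 3 of 6 for vehicle, 2 of 6 for MMI16 and 2 of 6 for Ami50.

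In edgeR's quasi-likelihood test of 6236 genes at GD21, 0 genes were called against vehicle for MMI8, MMI16, Ami25 or Ami50. At an unadjusted p under 0.05 there were 175, 210, 579 and 431 genes in that order, where chance alone gives about 312. DESeq2 called 0, 0 and 0 genes for MMI8, MMI16 and Ami25 and 22 for Ami50, all of them higher, where its own filter left 2245 genes to adjust over against 6235 in the other GD21 comparisons. Between the doses edgeR called 0 genes, with 394 at an unadjusted p under 0.05 for MMI16 against MMI8 and 203 for Ami50 against Ami25, and DESeq2 also called 0 in both. For Ami50 against MMI16 edgeR called 0 (451 at an unadjusted p under 0.05) and DESeq2 3. In simulated data the same test found 55.4% of genes changed 2-fold for MMI16 and 58.5% for Ami50, and 95.3% and 89.2% of genes changed 3-fold.

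At GD21 camera also called 2 lists each for Ami25, for MMI16 against MMI8 and for Ami50 against Ami25, and 0 for MMI8 and for Ami50 against MMI16, and none held with an estimated correlation. In Ami25 the leukocyte genes had a median log2 fold change of 0.58 (adjusted p = 7.3e-06, or 0.295 with an estimated correlation), and 5 of 16 rose when adjusted over the list alone. Genes of thyroid hormone receptors, transport and deiodinases had a median of -0.52 over 5 genes in Ami25 (adjusted p = 0.0293, or 0.295 with an estimated correlation). The extracellular matrix genes were higher at the upper dose of each compound, by a median of 0.40 for MMI16 against MMI8 (adjusted p = 0.0125, or 0.626) and 0.37 for Ami50 against Ami25 (adjusted p = 1.32e-05, or 0.761), the last value in each case with an estimated correlation. For MMI16 against MMI8 the leukocyte genes were also higher (median 0.44, adjusted p = 0.0276, or 0.626), and for Ami50 against Ami25 the thyroid hormone response genes were (median 0.31, adjusted p = 0.0148, or 0.062). Adjusted over the list alone, 1 matrix gene was higher for MMI16 against MMI8 and 1 thyroid hormone response gene for Ami50 against Ami25.

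The next question was how libraries labelled PD16 methimazole differed from PD16 vehicle, and the differences at 16 mg/kg were mostly falls. The embryonic globin share went against the stage label of the vehicle, MMI8 and MMI16 libraries alike. The directions are therefore between groups as labelled, and a methimazole effect cannot be told apart from a difference in age between these groups. Sox9, a transcription factor of progenitor and supporting cells, averaged 13.4 ± 8.54 CPM against 139 ± 51.7 CPM in vehicle (SD, n = 10 each), a fall of 11.7-fold (log2 fold change -3.55, SE 0.24). The Notch ligand gene Jag1 (-3.40), the potassium channel gene Kcnd2 (-3.70), the cold-inducible RNA-binding protein gene Cirbp (-3.43), the antiproliferative gene Tob1 (-3.43) and Qrich1 (-3.41) fell by a like amount. Each of these was below the vehicle mean in 10 of 10 libraries. The rises were small, with Pnn at 2.31-fold, Hmox2-ps1 at 2.00-fold, Lrrc47 at 1.75-fold, Dctd at 1.75-fold, Fbxw8 at 1.73-fold and Ethe1 at 1.72-fold.

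Members of several lists fell in PD16 MMI16, while camera, which sets a list against the other genes, called none of the lists. Over all 4906 genes tested, 356 fell and 42 rose. The falls among proliferation genes, Nrf2 targets and leukocyte genes were near that share. Of 10 endothelial genes 2 fell, Kdr (the receptor of vascular endothelial growth factor, log2 fold change -1.84) and Pecam1 (-1.96), and the list's camera adjusted p was 0.0989. Of 30 cell proliferation genes 2 fell, the replication helicase gene Mcm4 (-2.04) and the ribonucleotide reductase gene Rrm2 (-1.99), while Mki67 had a log2 fold change of 0.33 (adjusted p = 0.392). Of 9 immediate early and heat shock genes 2 fell, Jund (-2.97) and Hsph1 (-1.82). Of 26 genes of oxidative stress and Nrf2 targets 2 fell, Gsr (glutathione reductase, -2.71) and Sod1 (-0.60). In these 4 lists the counts adjusted over the list alone were 2, 2, 2 and 2. The macrophage receptor gene Mrc1 (-2.73) was the single called gene of 12 leukocyte genes, Srebf2 (-2.19), a regulator of cholesterol synthesis, of 21 cholesterol genes, and Cpt1a (-2.59), which imports fatty acids into mitochondria, of 4 thyroid hormone response genes. Adjusted over the list alone, 1 leukocyte gene and 1 cholesterol gene fell, and 1 thyroid response gene fell and 1 rose. Of 7 junction genes Gja1 fell (-1.13) and Cgnl1 rose (0.69), and 2 fell and 1 rose when adjusted over the list alone. The median and the mean log2 fold change differed in sign for cell proliferation (0.05 and -0.04), Nrf2 targets (0.04 and -0.11), leukocytes (0.14 and -0.07), cholesterol synthesis (0.11 and -0.06), thyroid hormone response (0.17 and -0.32) and junctions (0.28 and -0.02). None of the 13 steroidogenesis genes was called: Star had a log2 fold change of 0.01 (SE 0.19, adjusted p = 0.991), and Cat had 0.14 (SE 0.13, adjusted p = 0.686). In simulated data the test found 55.2% of genes changed 1.5-fold for MMI16 at PD16, so smaller changes can be missed.

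edgeR called 398 of 4906 genes for MMI16 at PD16, 42 higher and 356 lower, and 270 of the lower genes fell at least 2-fold. The 17 tested lists gave 0 camera calls for MMI16, where fry, which tests whether a list moves 1 way without comparing it with other genes, gave 2, endothelium (adjusted p = 8.55e-08) and immediate early and heat shock genes (4.59e-06), both lower. The higher count was less stable than the lower one, with 14 higher genes when only the compared libraries were fitted and 27 with no filter. Pnn had a log2 fold change of 0.69 (adjusted p = 0.294) and Hmox2-ps1 of 0.42 (adjusted p = 0.501) without the library with Alb at 200 CPM or more, and Lrrc47 of 0.61 (adjusted p = 0.114) and Fbxw8 of 0.70 (adjusted p = 0.0671) without MMI16 replicate 10, the library with the lowest total. Cgnl1 was not called without MMI16 replicate 10 (log2 fold change 0.65, adjusted p = 0.0637), without the library with Alb at 200 CPM or more (0.65, adjusted p = 0.0783) or with no filter (0.66, adjusted p = 0.115). Hmox2-ps1 is a pseudogene, and whether its counts include reads of its parent gene was not tested.

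At 8 mg/kg methimazole 410 genes were called in libraries labelled PD16, 72 higher and 338 lower. The higher count went to 27 with no filter, to 140 when only the compared libraries were fitted and to 45 without MMI8 replicate 63. Vtcn1, an immune checkpoint gene, fell 12.2-fold, from 57.6 ± 13.7 to 4.74 ± 3.39 CPM (SD, n = 10 each), and Cirbp fell 7.75-fold and Arhgap39 6.96-fold. Svs5 rose 3.19-fold, Crem 2.47-fold and Il33, an alarmin cytokine, 2.35-fold, and with no filter Svs5 (log2 fold change 1.64, adjusted p = 0.0681) and Il33 (1.20, adjusted p = 0.0551) were not called. Of 21 cholesterol synthesis genes 2 rose and 1 fell, and the list's median log2 fold change was 0.44 (camera adjusted p = 0.00499, or 0.752 with an estimated correlation). Of 10 endothelial genes 2 fell, with a median of -0.16 (camera adjusted p = 0.0196, or 0.209 with an estimated correlation). The counts adjusted over the list alone were also 2 higher and 1 lower for cholesterol synthesis and 2 lower for endothelium.

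The falls were deeper at the higher dose of methimazole. Against MMI8, MMI16 libraries had 93 lower and 9 higher genes among 4906, with 2 higher when only the compared libraries were fitted and 5 with the library number series as a covariate. The phosphatase gene Ptp4a2 was 3.05-fold lower (245 ± 83.9 against 717 ± 287 CPM, SD, n = 10 each), Traf3 3.32-fold lower and Dusp10 2.91-fold lower, each below the MMI8 mean in 10 of 10 libraries. Lrrc47 (2.00-fold) and Galm (1.83-fold) were higher, and without the library with Alb at 200 CPM or more Galm had a log2 fold change of 0.68 (adjusted p = 0.136). For Lrrc47 the log2 fold change was 0.81 (adjusted p = 0.101) without MMI16 replicate 10. The cholesterol synthesis genes had a median of -0.38 (camera adjusted p = 4.02e-07, or 0.59 with an estimated correlation), the steroidogenesis genes of -0.06 (adjusted p = 0.0406, or 0.59) and the extracellular matrix genes of 0.32 (adjusted p = 0.00155, or 0.59). Over all genes tested 0 members of these lists were called by edgeR, and adjusted over the list alone 2 steroidogenesis genes fell.

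**Figure D3:**
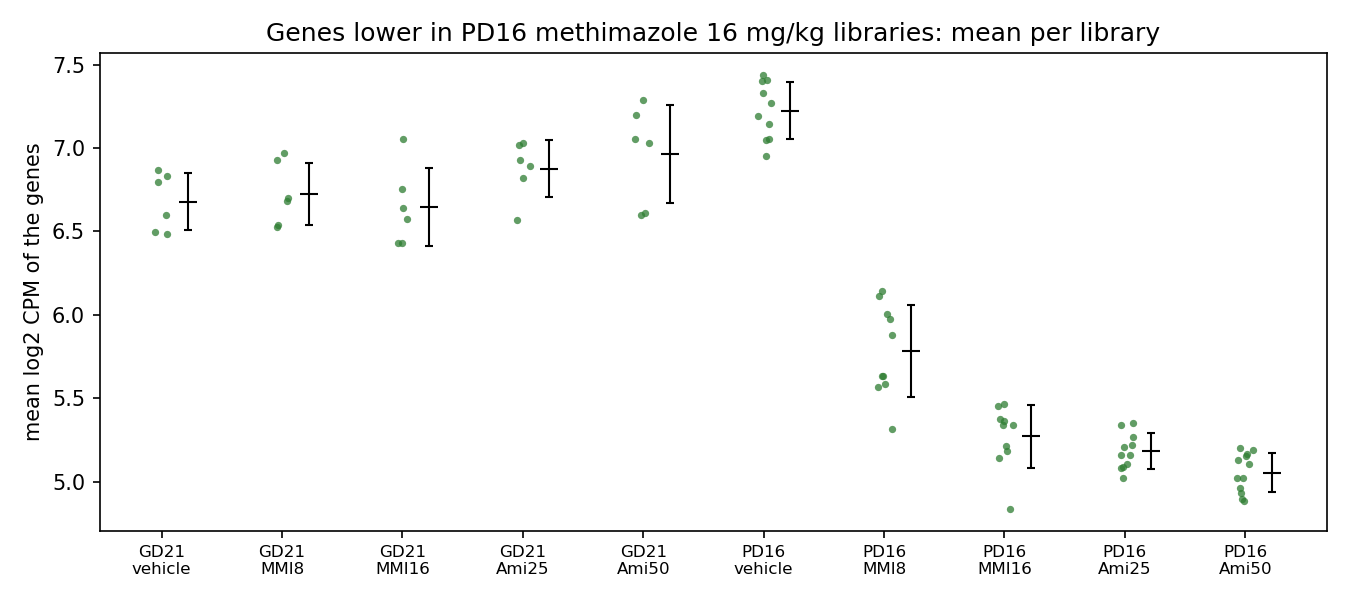
Mean log2 CPM (vertical axis) of the 270 genes that fell at least 2-fold in libraries labelled PD16 MMI16, with 1 green point per library and a black mark for the group mean and SD, in the 10 labelled groups (horizontal axis). The PD16 vehicle libraries average 7.22, the treated PD16 groups 5.05 to 5.78 and the GD21 groups 6.65 to 6.96.

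Libraries labelled PD16 amitrole differed from PD16 vehicle far more widely, and in both directions. Over all 4906 genes tested, 1329 were higher and 1298 lower in Ami50, the share against which its list counts are to be read. The directions are between groups as labelled. The embryonic globin share above went against the stage label of the PD16 vehicle libraries. Eif2s3y, the only Y-linked marker gene used here, went against the implied male sex in 8 of the 12 Ami50 libraries and in 0 of the 11 Ami25 libraries. All 23 PD16 amitrole libraries correlated more with the GD21 vehicle mean than with the PD16 vehicle mean. Amitrole effects in these comparisons can therefore not be told apart from a stage difference. In Ami50 the embryonic globin genes Hbz and Hbe1 were 62.7-fold and 46.9-fold lower, from 660 ± 160 to 10.1 ± 7.33 CPM and from 4896 ± 1160 to 99.7 ± 53.1 CPM (SD, n = 10 and 12), while the adult beta globin gene Hbb-b1 was 3.78-fold higher. Sox9 (24.3-fold), Vtcn1 (24.9-fold), the actin-bundling gene Fscn1 (23.6-fold) and Calb2 (21.0-fold) were also lower. The neutrophil genes S100a8 (17.8-fold) and RatNP-3b (12.9-fold), the matrix gene Dpt (13.2-fold), Mia (13.5-fold) and Qrfpr (14.1-fold) were higher, each above the vehicle mean in 12 of 12 libraries. Alb was 13.7-fold higher (log2 fold change 3.78, SE 1.07), above the vehicle mean in 5 of 12 libraries. Without the libraries with Alb at 200 CPM or more its log2 fold change was -0.14 (adjusted p = 0.78).

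Steroid genes were higher and cholesterol synthesis genes lower in libraries labelled PD16 Ami50 than in PD16 vehicle. GD21 vehicle differed from PD16 vehicle in the same directions. Star, for example, averaged 953 ± 131 CPM in PD16 Ami50, 983 ± 57.5 CPM in GD21 vehicle and 341 ± 84.9 CPM in PD16 vehicle (SD, n = 12, 6 and 10). Of 13 steroidogenesis genes 10 rose and 2 fell (11 and 2 adjusted over the list alone), with Cyp11a1, which cuts the cholesterol side chain, at 20160 ± 5480 against 6612 ± 1140 CPM (3.20-fold; SD, n = 12 and 10). Tspo (3.79-fold), Star (2.97-fold) and the electron carrier gene Fdxr (2.54-fold) rose with it. The list's camera adjusted p was 0.0017, or 0.17 with an estimated correlation. Of 21 cholesterol synthesis genes 18 fell and 1 rose, both over all genes and adjusted over the list alone, among them Srebf2 (6.48-fold), Fdps (2.99-fold) and Hmgcs1 (2.99-fold; camera adjusted p = 0.00882, or 0.426 with an estimated correlation). The 6 cortex genes summed to 31600 ± 9960 CPM in Ami50 and 13800 ± 2300 CPM in vehicle (SD). Within Ami50 the sum was 37400 ± 5980 CPM in the 8 libraries with Eif2s3y under 10 CPM and 20200 ± 4310 CPM in the other 4 (SD), without overlap. The 4 were replicates 17 to 20 and the 8 were replicates 37 to 40 and 83 to 86. Eif2s3y and the library number series can therefore not be told apart here. In Ami25, with Eif2s3y at 62.9 CPM or more in every library, the sum ranged from 6300 to 39800 CPM. Without the 8 libraries the log2 fold changes were 1.26 for Cyp11a1, 1.79 for Tspo, 1.62 for Star and 1.53 for Fdxr, all still called.

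Proliferation genes were lower in the same libraries. Of 30 such genes 25 fell and 1 rose, both over all genes and adjusted over the list alone, with Mcm4 9.52-fold, Rrm2 7.76-fold and the mitotic activator Cdc20 1.98-fold lower. This was the list that held with an estimated correlation (camera adjusted p = 5.11e-08, or 0.00774). Mki67 had a log2 fold change of -0.30 (SE 0.18, adjusted p = 0.166). Of 6 retinoic acid genes 4 fell, also over the list alone, among them Crabp1 (14.3-fold), Crabp2 (2.59-fold) and Rbp4 (1.67-fold; list camera adjusted p = 0.124). Of 10 endothelial genes 5 fell, also over the list alone, with Pecam1 4.86-fold, Kdr 2.77-fold and Emcn 1.90-fold lower (camera adjusted p = 0.0117, or 0.16 with an estimated correlation). Of 9 immediate early and heat shock genes 3 fell and 1 rose, also over the list alone, with Jund 9.24-fold, Hsph1 5.01-fold and Hsp90aa1 1.82-fold lower (camera adjusted p = 0.124; median 0.09, mean -0.53).

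Genes of leukocytes, matrix and antioxidant defence were higher in PD16 Ami50. Of 12 leukocyte genes 11 rose and 1 fell, also over the list alone, with the complement gene C1qc 4.67-fold and the lysozyme gene Lyz2 3.45-fold higher and Mrc1 2.16-fold lower (camera adjusted p = 0.0089, or 0.286 with an estimated correlation). Of 21 matrix genes 11 rose and 1 fell, also over the list alone, among them Mfap5 (10.4-fold), the elastin gene Eln (3.55-fold) and Col5a2 (1.99-fold; camera adjusted p = 0.027, or 0.426). Of 26 oxidative stress and Nrf2 genes 16 rose and 4 fell, also over the list alone, with the ferritin gene Fth1 2.74-fold and Taldo1 1.49-fold higher and Gsr 7.46-fold lower (camera adjusted p = 0.0117, or 0.169). Cat, which encodes the catalase that amitrole inhibits, averaged 183 ± 28.4 CPM against 103 ± 25.9 CPM (1.87-fold; SD, n = 12 and 10). Of 13 erythroid genes 10 rose and 3 fell, also over the list alone, and their median (1.49) and mean (0.14) log2 fold changes lay far apart (camera adjusted p = 0.0557).

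Smaller lists gave no camera call in PD16 Ami50. The lists keep the names of testis cells that were chosen in advance. With testis genes at trace levels, these names identify no cell type in these libraries. All 3 xenobiotic genes rose, Ephx1 3.45-fold, Sult1a1 2.39-fold and Por 1.38-fold (adjusted p = 0.0557), and 2 of 4 smooth muscle genes rose, Tagln 3.53-fold and Myl9 1.81-fold (0.261). Of 9 fetal and stem Leydig genes 1 rose, the growth factor gene Igf1 at 3.89-fold, and 5 fell, among them Pdgfra 2.86-fold and Nes 3.21-fold (0.314). Of 8 Sertoli genes of the maturing list 4 rose, among them the lysosomal gene Ctsl 2.37-fold and Clu 2.79-fold, and 2 fell, among them Inha 2.37-fold (0.38). Of 7 junction genes 3 rose, among them F11r 2.46-fold and Cgnl1 2.77-fold, and 2 fell, among them Cdh2 1.96-fold (0.604; the median of -0.09 and the mean of 0.16 differed in sign). Of 4 thyroid hormone response genes 2 rose, Me1 2.77-fold and Ucp2 2.15-fold, and Cpt1a fell 3.26-fold (0.648). Of the 3 gonocyte and spermatogonia genes Ccnd2 rose 1.82-fold, Upp1 rose 1.86-fold and Uchl1 fell 1.40-fold (0.506). Adjusted over the list alone the counts were the same, apart from 1 more lower fetal and stem Leydig gene. In lists with too few tested genes for a list test Ncam1 fell 2.57-fold and Ybx3 rose 1.84-fold, above the vehicle mean in 6 of 12 libraries.

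edgeR called 2627 of 4906 genes for PD16 Ami50, 1329 higher and 1298 lower. Without the 8 libraries with Eif2s3y under 10 CPM it called 2356, of which 1944 were among these, and Me1 (log2 fold change 0.92, adjusted p = 0.0704), Upp1 (0.75, adjusted p = 0.12), Uchl1 (-0.24, adjusted p = 0.519), Rbp4 (-0.24, adjusted p = 0.642) and Por (0.52, adjusted p = 0.0925) were not called. The globin genes are near-identical copies in part, and how reads were assigned among them is not given in the sources used here.

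The lower dose of amitrole gave similar changes in libraries labelled PD16. In Ami25 Mia (14.0-fold), Qrfpr (12.9-fold) and Dpt (12.1-fold) were the largest rises and Hbz (49.6-fold), Hbe1 (31.1-fold) and Akr1c3 (23.6-fold) the largest falls. Of 30 proliferation genes 28 fell and 1 rose (camera adjusted p = 1.08e-08, or 0.00399 with an estimated correlation), and 29 fell when adjusted over the list alone. Of 13 steroidogenesis genes 10 rose and 2 fell (0.0033, or 0.252), of 21 cholesterol synthesis genes 1 rose and 18 fell (0.0033, or 0.433), and of 12 leukocyte genes 11 rose and 1 fell (0.00697, or 0.253), with the same counts adjusted over the list alone. Of 21 matrix genes 14 rose (0.0109, or 0.433), of 10 endothelial genes 5 fell (0.027, or 0.202), of 13 erythroid genes 10 rose and 3 fell (0.027, or 0.433), all 3 xenobiotic genes rose (0.048, or 0.202), and the counts over the list alone were the same. Of 26 oxidative stress and Nrf2 genes 16 rose and 3 fell, or 17 and 3 over the list alone (0.0182, or 0.202). edgeR called 2717 genes, 1369 higher and 1348 lower. Ami50 against Ami25 gave 0 genes by edgeR and 0 by DESeq2, with 230 at an unadjusted p under 0.05, where chance gives about 245. Neither method called Eif2s3y, at 30 ± 43 CPM in Ami50 and 79.2 ± 15 CPM in Ami25 (SD, n = 12 and 11). With so wide a spread within Ami50, the 0 calls do not show that the doses were alike. Without the 8 Ami50 libraries with Eif2s3y under 10 CPM edgeR called 11, 10 higher and 1 lower in Ami50, and it called 1 with no filter and 1 at a mean of 10 CPM.

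The overlap between the compounds was examined through the genes called for both at PD16, with the same doubt about the stage labels and the implied sex. Of the 398 genes called for MMI16, 357 were also called for Ami50, 16 higher and 341 lower in both, with a further 3 called in opposite directions. Sox9, Mcm4, Rrm2, Srebf2, Kdr, Pecam1, Mrc1, Jund and Gsr fell in both, and so did Jag1 (log2 fold change -3.95 in Ami50) and Cirbp (-3.36 in Ami50). Independent lists of these sizes would share 11.4 higher and 94.2 lower genes. With the vehicle libraries divided between the compounds the overlap was 327 to 338 genes (median 330.5 over 10 splits), 1 to 8 of them higher (2.19 to 6.2 from independent lists of those sizes) and 323 to 334 lower (71.3 to 82.8). Simulated groups with no effect, set against a shared vehicle group that was simulated too, had at most 1 gene in common. The simulation drew each gene on its own, without correlation between genes, so it can understate what unchanged groups share. The fold changes correlated across the 4906 genes, which are not independent replicates, with r = 0.668 (0.583 with divided vehicle libraries, 0.495 in the simulation). The covariance was 0.347 (0.324 with divided vehicle libraries) against a simulated 0.0199 (0.0181 to 0.0212), a difference of 0.327. Neither the divided libraries nor the simulation tests a stage difference. Of the 270 genes at least 2-fold lower in MMI16, 167 were higher and 11 lower in PD16 vehicle than in GD21 vehicle. The vehicle group alone could thus give part of the shared falls, although 260 of the 270 were called lower in PD16 Ami50 than in GD21 Ami50. At GD21 0 genes were shared, and the covariance of 0.0346 lay -0.00945 from the simulated 0.044 (r = 0.43, or -0.274 with divided vehicle libraries, against a simulated 0.491).

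The compounds were also set against each other directly at their higher doses, 50 mg/kg for amitrole and 16 mg/kg for methimazole, in libraries labelled PD16. Hbz (82.0-fold), Hbe1 (50.8-fold), Crabp1 (13.5-fold), Akr1c3 (9.07-fold), Hbg1 (7.97-fold) and Akr1c14 (5.48-fold) were lower in Ami50, and Dpt (19.2-fold), the neutrophil gene S100a9 (12.2-fold), Qrfpr (11.7-fold), the glutathione transferase gene Gsta1 (11.2-fold), Mfap5 (11.2-fold) and Mia (11.1-fold) were higher. Of 30 proliferation genes 27 were lower and 1 higher (28 and 1 adjusted over the list alone), with Cdc20 2.14-fold, Mcm7 2.16-fold and Cdk1 1.92-fold lower (camera adjusted p = 4.46e-13, or 0.000382 with an estimated correlation). Of 26 oxidative stress and Nrf2 genes 16 were higher and 2 lower (17 and 2 over the list alone), with Fth1 2.55-fold, Sod2 2.71-fold and Gpx1 1.93-fold higher (camera adjusted p = 0.000167, or 0.0288).

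Further lists differed between Ami50 and MMI16 at PD16 and did not hold with an estimated correlation. Of 13 steroidogenesis genes 9 were higher and 2 lower, also over the list alone, with Tspo 3.52-fold, Fdxr 2.52-fold and Cyb5a 2.13-fold higher (camera adjusted p = 3.12e-05, or 0.0681). Of 21 cholesterol synthesis genes 1 was higher and 18 lower (1 and 19 over the list alone), with Fdps 3.23-fold, Hmgcs1 3.08-fold and Mvk 2.15-fold lower (3.12e-05, or 0.356). Of 12 leukocyte genes 11 were higher (12 over the list alone), with Lyz2 3.24-fold, Mrc1 3.06-fold and Lyve1 2.06-fold higher (3.12e-05, or 0.0681). Of 6 retinoic acid genes 4 were lower, 5 over the list alone (0.0278, or 0.182), of 3 xenobiotic genes 2 were higher, 3 over the list alone (0.0479, or 0.0769), and of 13 erythroid genes 10 were higher and 3 lower, also over the list alone (0.0482, or 0.46, with a median of 1.38 and a mean of -0.04). The gap junction gene Gja1 (2.05-fold) and F11r (2.63-fold) were higher and the endothelial claudin gene Cldn5 (2.89-fold) lower. Tf, an iron carrier made in liver, was 7.67-fold higher, at 437 ± 655 against 52.6 ± 40.7 CPM (SD, n = 12 and 10), in groups with 3 and 1 libraries with Alb at 200 CPM or more. edgeR called 2331 of 4906 genes, 1107 higher and 1224 lower. Without the libraries with Eif2s3y under 10 CPM, Cpt1a (log2 fold change 0.49, adjusted p = 0.269), Sox9 (-1.30, adjusted p = 0.0903) and Rbp4 (-0.56, adjusted p = 0.252) were not called.

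The vehicle libraries of both labelled stages were compared to see how they differ without dosing. The direction rests on stage labels that the embryonic globins went against. Hbz (77.7-fold), Hbe1 (36.7-fold) and Akr1c3 (32.4-fold) were higher in libraries labelled PD16, and the liver genes Fga (126-fold), Fgb (63.2-fold) and Gc (57.2-fold) were lower. In GD21 vehicle Fga, Fgb and Gc averaged 111 ± 167, 251 ± 385 and 80.9 ± 141 CPM (SD, n = 6), a spread larger than each mean. Alb was at 200 CPM or more in 3 of the 6 GD21 vehicle libraries and in 0 of the 10 PD16 vehicle libraries. Of 30 proliferation genes 26 were higher in PD16 and 0 lower (26 and 1 adjusted over the list alone; camera adjusted p = 1.17e-16, or 0.000205 with an estimated correlation), and all 4 xenobiotic genes were lower, also over the list alone (0.00727, or 0.0306). Of 21 cholesterol synthesis genes 16 were higher and 1 lower (18 and 1 over the list alone; 0.00171, or 0.412). Of 15 steroidogenesis genes 2 were higher and 10 lower, also over the list alone (2.49e-05, or 0.0619), of 26 oxidative stress and Nrf2 genes 2 were higher and 14 lower (5 and 14 over the list alone; 0.00171, or 0.0619), of 14 leukocyte genes 13 were lower, also over the list alone (8.53e-06, or 0.0619), and of 16 erythroid genes 3 were higher and 12 lower, also over the list alone (0.00171, or 0.381). In each of these lists most called genes differed from PD16 vehicle in the same direction in GD21 vehicle and in PD16 Ami50. For these lists an amitrole effect at PD16 cannot be told apart from a stage difference. edgeR called 2923 of 6287 genes, 1533 higher and 1390 lower in PD16.

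Whether the effect of each compound differed between the labelled stages was tested as an interaction, with the same doubt about the stage labels. For MMI16 it was called for 328 of 6287 genes, 321 with a more negative and 7 with a more positive change at PD16 (12 more positive with DESeq2's size factors, 4 with the legacy fit and 11 without MMI16 replicate 10), led by Jag1 (-3.76 log2), Sox9 (-3.74) and Cirbp (-3.58). Shc1 (3.04), Pnisr (0.74) and Map2k3 (0.60) had the most positive differences. With no filter Pnisr (0.76, adjusted p = 0.0845) and Map2k3 (0.62, adjusted p = 0.0864) were not called. Map2k3 also lost its call under other alternatives, among them the fit without the libraries with Alb at 200 CPM or more (0.56, adjusted p = 0.214). For Ami50 2059 genes were called, 1029 with a more positive and 1030 with a more negative change at PD16. Hbz (-6.99), Hbe1 (-6.61) and Vtcn1 (-5.58) had the most negative differences and the liver genes Fga (6.28), Bhmt (5.10) and Serpinc1 (5.09) the most positive, and Alb was at 200 CPM or more in 3 of 12 PD16 and 2 of 6 GD21 Ami50 libraries and in 3 of 6 GD21 vehicle libraries. Of 30 proliferation genes 22 had a more negative difference (24 adjusted over the list alone; camera adjusted p = 3.01e-09, or 0.0156 with an estimated correlation), and of 15 steroidogenesis genes 10 had a more positive and 1 a more negative one, also over the list alone (0.000677, or 0.155). Cholesterol synthesis (1 more positive and 14 more negative of 21, or 1 and 16 over the list alone; 0.00423, or 0.502), xenobiotic metabolism (3 more positive of 4, also over the list alone; 0.0493, or 0.132) and endothelium (1 and 4 of 12, also over the list alone; 0.0424, or 0.155) were the other lists called for Ami50. The 20 lists gave 0 camera calls for MMI16 and 5 for Ami50.

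**Figure D4:**
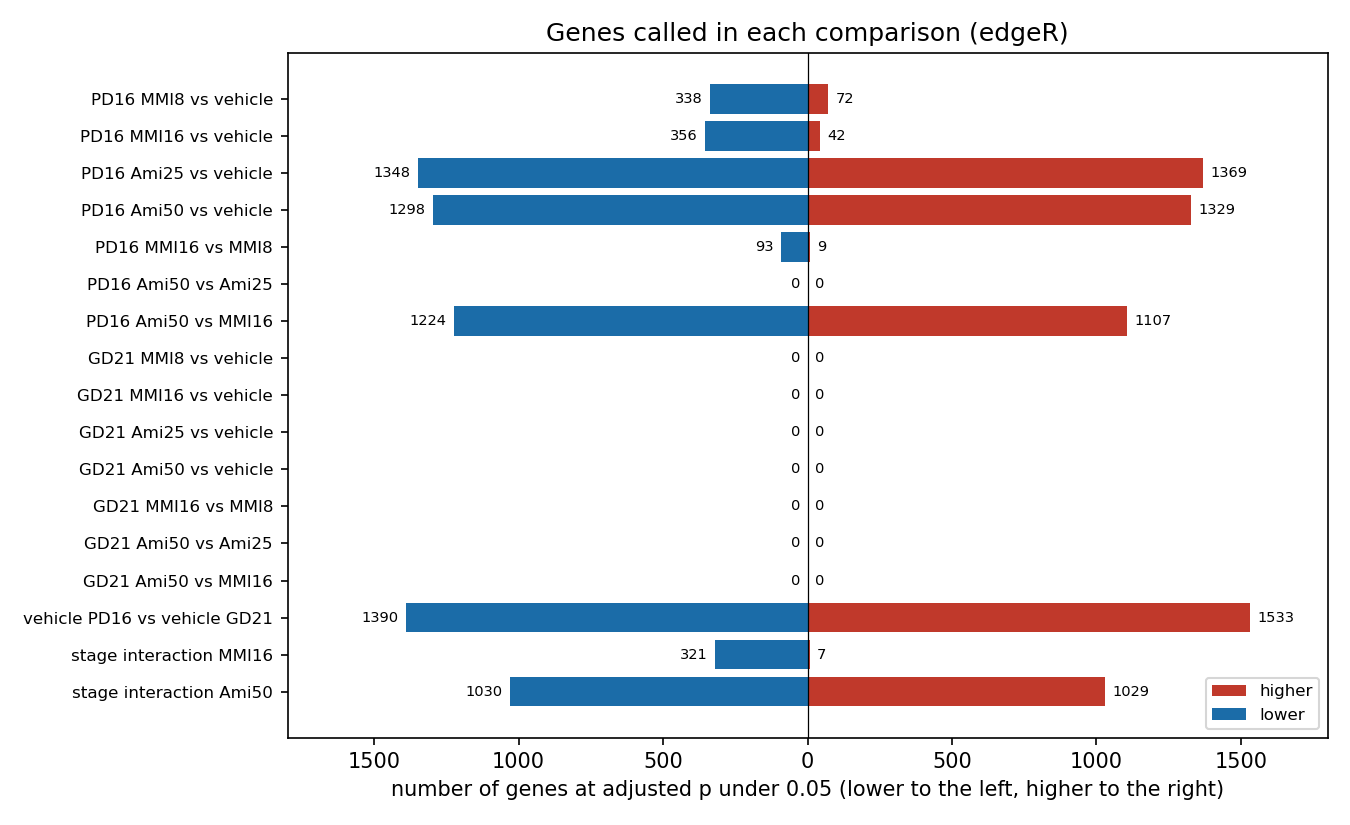
Number of genes called at an adjusted p under 0.05 by edgeR in each of the 17 comparisons, lower to the left and higher to the right of 0 (horizontal axis), with the count printed at each bar. The comparisons at GD21 and Ami50 against Ami25 at PD16 have 0 genes, and the amitrole comparisons with vehicle at PD16 have 2627 and 2717.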

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

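Of the tests in this part, the other splits of the libraries and the test of genes that fall after birth in PD16 vehicle were written before their values were seen. The tests of admixture, ribosomal protein genes, adrenal genes, blood, the stage of the amitrole libraries, total counts, differences within groups and dose, the test of genes that fall after birth in the methimazole groups, with the marker lists and the 270 falling genes, were chosen after the result was seen. For the correlation of the amitrole effects between stages, no bound was set at first, and its bounds, with the companion count of 23 libraries, were set after both values had been seen.

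The first pattern was the low level of testis genes with abundant adrenal genes. Adrenal RNA mixed into testis RNA was argued against by the testis genes, which reached at most 0.0199% of the adrenal cortex genes in any group mean. Counts set against the wrong gene names were argued against by 70 ribosomal protein genes among the 200 most abundant, where 0.938 would be drawn by chance. Libraries of adrenal gland stayed open, with 14 of the 15 adrenal genes at 10 CPM or more in every group. No biological explanation was tested, since the design gives none.

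The next pattern was that libraries labelled PD16 amitrole resembled the GD21 libraries while the other PD16 libraries carried embryonic globins. A larger amount of the same blood would not change the embryonic share of globin counts. All 10 PD16 vehicle libraries had a share above every GD21 vehicle library, which argues against more blood as the source of the embryonic globins only. The share is part of the pattern and does not measure the amount of blood. All globins took 8.93 ± 2.28% of counts in GD21 vehicle, 8.86 ± 1.83% in PD16 Ami50 and 3.81 ± 0.451% in PD16 vehicle (SD). Whether more blood gave part of the resemblance was not tested. Of genes that fall after birth, 4 of the 8 tested (Plagl1, Igf2bp2, Peg3 and Dlk1) were higher and 0 lower in PD16 vehicle than in GD21 vehicle, which leaves open that the PD16 vehicle libraries came from younger animals, although Igf2 (-0.08), H19, Mest and Cdkn1c were not called. Hmga2, Igf2bp1 and Igf2bp3 were also on this list of 11 genes and were too low to pass the filter. For the methimazole libraries, younger animals cannot be told apart from other causes: against GD21 vehicle 2 of the 8 genes were higher and 1 lower in MMI16, and 1 higher and 2 lower in MMI8. Plagl1 was lower in both, at 139 ± 47.3 CPM in MMI16 and 186 ± 57.8 CPM in MMI8 against 269 ± 71.4 CPM in GD21 vehicle and 627 ± 166 CPM in PD16 vehicle (SD). Plagl1 also met the rule of the 270 falling genes weighed below. Its values in the vehicle, methimazole and amitrole groups are therefore not evidence separate from those genes. Against separate sets of PD16 vehicle libraries, PD16 Ami50 and GD21 Ami50 correlated with a median r of 0.711 (0.701 to 0.743) over 6440 genes, which leaves open that the PD16 amitrole libraries were of the GD21 stage. The 2 groups were not alike throughout, since 494 of 6287 genes were called between PD16 Ami50 and GD21 Ami50, 260 of the 270 falling genes weighed below among them. Plagl1, itself among the 270, was at 81.6 ± 19.6 CPM in PD16 Ami50 against 310 ± 86.9 CPM in GD21 Ami50 (SD). Over 2606 genes called for PD16 Ami50, the Ami50 fold changes at PD16 and at GD21 correlated with r = -0.257. This cannot decide on an amitrole effect alike at both stages. The PD16 fold changes also carry any stage difference, and edgeR called 0 genes for Ami50 at GD21. An effect specific to PD16 cannot be told apart from a stage difference either, since all 23 PD16 amitrole libraries and 0 of the other 30 lay closer to the GD21 vehicle mean.

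The last pattern was that the 270 genes chosen for their fall in PD16 MMI16 were also lower in the other treated PD16 groups (252 called lower in MMI8, 264 in Ami25 and 262 in Ami50, with medians of -1.40, -1.96, -2.18 and -2.28 in MMI8, MMI16, Ami25 and Ami50) and not at GD21 (-0.01 to 0.33). A difference in total counts was argued against, since the median for MMI16 was -2.01 with the total as a covariate and 270 genes were still called. Technical differences of the kind that also act within groups were argued against, since with the genes chosen on 5 vehicle and 5 MMI16 libraries at PD16, the lowest of the other 5 vehicle libraries lay above the highest of the other 5 MMI16 libraries, in the mean of the genes, by at least 8.33 SDs within PD16 groups in 10 divisions. Differences within groups were present, as these genes correlated there with their own mean at a median of 0.604 at GD21 and 0.379 at PD16. Their mean correlated with the log total at -0.705 and -0.575. Whether these differences were technical or lay between animals was not tested. A technical difference that coincides with the groups was not tested. A methimazole effect that grows with dose stayed open: of 221 genes chosen for a fall of at least 2-fold in MMI8, a choice that works against it, 161 were lower at 16 than at 8 mg/kg.

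Other splits of the same libraries gave at most 154 calls for PD16 MMI8 (real 410), 76 for MMI16 (398), 1210 for Ami25 (2717), 1660 for Ami50 (2627), 36 for MMI16 against MMI8 (102) and 1139 for Ami50 against MMI16 (2331). Of 100 splits in each, the real one included, 1 reached the real count, so a random grouping of single libraries rarely gives such counts. For the comparison of vehicle libraries between stages (2923, highest other 1651) and the interactions for MMI16 (328, highest other 30) and Ami50 (2059, highest other 1072), 1 of 60 splits reached the real count. The splits treat libraries as independent, while litters are not given. Litter differences that follow the groups were therefore not tested, and chance at the level of litters cannot be excluded. With a real count of 0 all 100 splits are as large by construction, so the splits say nothing on the 0 calls of PD16 Ami50 against Ami25 (highest other 178) and of the GD21 comparisons, with highest others of 14, 2, 1 and 575 for MMI8, MMI16, Ami25 and Ami50 against vehicle, 2 for MMI16 against MMI8, 15 for Ami50 against Ami25 and 562 for Ami50 against MMI16. The 575 and 562 calls are the highest of 100 splits each, most of which gave 0, and point to a structure of these libraries that was not tested further.

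Single libraries lay far from their group in 9 of 72 tests (9 measures), where chance gives about 1 in 20. Total counts were 1627000 in GD21 vehicle replicate 41 and 1053000 in PD16 vehicle replicate 22. The embryonic share of globin counts was 0.878% in GD21 Ami50 replicate 88. Alb was 5319 CPM in GD21 vehicle replicate 44, 10980 in MMI8 replicate 45, 1843 in Ami25 replicate 81, 4394 in Ami50 replicate 89 and 507.2 in PD16 MMI16 replicate 9. The mean log2 CPM of the 270 falling genes was 4.837 in PD16 MMI16 replicate 9. The effect differed between the labelled stages by the interaction test for 328 genes with MMI16 and 2059 with Ami50.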

How the results depend on the processing

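Of the counts of calls under the alternatives, 182 stayed within 1.5 times the reported value and 20 moved. PD16 Ami50 against Ami25 went from 0 to 1 with no filter, 1 at a mean of 10 CPM and 11 without libraries with Eif2s3y under 10 CPM, an alternative chosen after seeing the data. With DESeq2's Wald test and filter GD21 Ami50 against vehicle went from 0 of 6236 genes to 22 of 2245 and Ami50 against MMI16 from 0 to 3. Lists called by camera went, with an estimated correlation, from 7 to 1 for PD16 Ami50, from 8 to 2 for Ami50 against MMI16, from 7 to 2 for the vehicle stage comparison, and from 1 to 0 for GD21 MMI16 and from 1 to 0 for GD21 Ami50. With fry, directional, they were 2, 15, 17 and 16 for PD16 MMI16 (0 by camera), PD16 Ami50, Ami50 against MMI16 and the vehicle comparison, and 0 and 0 for GD21 MMI16 and Ami50. With fry, mixed, they were 5 for PD16 MMI16, 13 for PD16 Ami50 and 0 and 0 for the GD21 groups. The cause was not tested. Calls ranged from 338 to 454 for PD16 MMI16, 379 to 477 for MMI8, 2546 to 3425 for Ami25, 2355 to 3322 for Ami50, 68 to 111 for MMI16 against MMI8, 1883 to 2736 for Ami50 against MMI16, 2475 to 3136 for the vehicle comparison, and 284 to 334 and 1604 to 2101 for the MMI16 and Ami50 interactions. Of 2134 values of named genes, 2079 kept direction and call, 54, of 20 results in 18 genes, lost the call and 1 reversed: Alb in PD16 Ami50 at -0.14 (adjusted p = 0.78) without libraries with Alb at 200 CPM or more, which removes by construction the libraries that gave the rise. Library numbers are unique across groups, so no paired analysis was possible because the labels pair nothing. Median totals of 492083 at PD16 and 963356 at GD21 limited tests of genes of a few CPM.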

Other observations

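Genes that fall after birth also differed within the libraries labelled PD16. Plagl1, an imprinted growth regulator, was lower than in vehicle in all treated groups, by a log2 fold change of -1.78 in MMI8 (adjusted p = 3.31e-15), -2.28 in MMI16 (2.54e-19), -2.78 in Ami25 (2.69e-23) and -2.85 in Ami50 (2.82e-24). Igf2bp2 was lower in MMI8 (-0.66, adjusted p = 0.0406), Ami25 (-1.49, adjusted p = 8.88e-08) and Ami50 (-1.62, adjusted p = 1.16e-08) and not called in MMI16 (-0.57, adjusted p = 0.0849). Igf2 was lower in Ami25 (-0.88, adjusted p = 0.00128) and Ami50 (-0.94, adjusted p = 0.000507), and so was Dlk1 (-0.48, adjusted p = 0.0125, and -0.51, adjusted p = 0.00725). Cdkn1c (-0.11 and -0.21), H19 (0.01 and -0.18), Mest (-0.79 and -0.08) and Peg3 (-0.32 and -0.41) were not called in Ami25 or Ami50. Cyp21a1 averaged 9690 ± 2450 CPM and Pnmt 723 ± 113 CPM in PD16 Ami50 (SD, n = 12).

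Of the 270 falling genes, 167 were higher and 11 lower in PD16 vehicle than in GD21 vehicle (median 0.634). Without the 8 libraries with Eif2s3y under 10 CPM, PD16 Ami50 against vehicle gave 2356 calls. Eif2s3y averaged 30 ± 43 CPM in PD16 Ami50 and 82.6 ± 16.5 CPM in PD16 vehicle.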
